A study of Homo sapiens with 12 samples.

How the data were processed

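Gene expression was measured by RNA sequencing in 12 libraries of T47D cells, with 3 replicates in each of 4 groups formed by genotype (control or ectopic HOXB13) and treatment (ethanol vehicle or 2 nM estradiol for 24 h). Cells were kept in medium with 10% charcoal-stripped serum for 72 h before treatment. Per the labels, RNA was extracted with an RNeasy kit, and libraries were prepared and sequenced by a service provider. The deposited table holds raw counts per gene symbol, with a column for each library. Its values were whole numbers whose sums differed between libraries, and every column was mapped to a sample. The submitters' notes name FastQC, STAR, Picard and HTSeq and the genome builds GRCh37 and hg19. Tool versions, the annotation release and the strand setting are not given in the sources used here. The table has no coordinates, so genes are given by symbol alone.

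Of 55882 symbols, 30284 had no count in any library. Genes were kept by edgeR's filterByExpr by group (minimum count 10, minimum total count 15), which left 14799, holding at least 99.9% of the counts of every library. Libraries were scaled by TMM factors between 0.974 and 1.04. Levels are CPM from TMM-effective library sizes, given as mean ± SD over 3 libraries, and log2 CPM used a prior count of 2. Depth was 17679824 to 21385996 counts per library. Ratios for HOXB13, which had 0 to 3 counts in a control group, were taken from summed counts with an exact 95% interval, and against a floor of 3 counts over the group where the sum was 0.

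Differences were tested with edgeR 4.0.16 in R 4.3.3, with a group-means fit over all 12 libraries, the robust quasi-likelihood F test and Benjamini-Hochberg adjustment at 0.05 over all tested genes of each comparison. The 5 comparisons were estradiol against vehicle in control cells and in HOXB13 cells, HOXB13 against control cells in vehicle and in estradiol, and the interaction, which is the difference between the estradiol responses. The labels do not say whether replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical in part. An exact permutation of 3 against 3 libraries cannot give a two-sided p below 0.1, so no such test of single values was used. The response ratio is the slope through the origin of the HOXB13 on the control log2 fold changes over genes with an average estradiol effect past the threshold, which does not favour either genotype in the selection.

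The replicate numbers were checked for pairing by correlating, across genes, the deviations of equally numbered libraries from their group means. The correlations were 0.132 to 0.457 for estradiol in control cells, 0.184 to 0.354 for estradiol in HOXB13 cells, 0.125 to 0.409 for HOXB13 in vehicle and 0.123 to 0.311 for HOXB13 in estradiol, all above the minimum of 0.1. Values with the replicate number as a block are therefore given beside these comparisons. Over the 18 pairs of the interaction the lowest was 0.0926, so its fit was not treated as paired. Libraries with different numbers had correlations of −0.354 to 0.255. Deviations cancel out within a group, so a shift shared by libraries numbered 2 alone also makes numbers 1 and 3 correlate. In each comparison between 2 groups, number 2 had the highest value, and numbers 1 and 3 had 0.123 to 0.293. The check therefore cannot tell matching of every number from a difference of number 2 alone, so using the block does not show matched libraries. The labels do not say what the numbers stand for.

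Gene lists were written before the data were examined, as were the comparisons, the naming rule and all alternatives not named as added. The 20 lists were estrogen-induced genes, estrogen-repressed genes, DNA replication and G1/S genes, mitosis and G2/M genes, ribosome biogenesis genes, luminal identity genes, basal and myoepithelial genes, mesenchymal transition genes, androgen receptor targets and prostate luminal genes, type I interferon response genes, NF-kB and inflammatory cytokine genes, cholesterol synthesis genes, fatty acid synthesis genes, unfolded protein response genes, hypoxia and glycolysis genes, p53 target and senescence genes, HOX cluster genes, HOX cofactor genes, non-epithelial cell markers and epithelial cells of other origin. The 19 lists with at least 5 tested members were tested as sets with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over lists. Members adjusted over the list alone face fewer tests than over all genes, so more of them can pass. In 17 cases of a list in a comparison, the median, the mean and the test differed in sign, and 0 of these passed the threshold.

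Genes were named by a fixed rule. It named HOXB13, ESR1, PGR, GREB1, TFF1, IL17RB, FOXA1, GATA3, CCND1 and MYC in any case. In each comparison between 2 groups it named up to 8 genes per direction with the largest log2 fold change among those past the threshold, with an average log2 CPM of at least 1, an approved-style symbol and replicates that did not overlap. It also named up to 4 members of each list past its set test and up to 2 passing members of each other list. Genes that report the sex of the donor were not named, and some other genes that the rule names are not reported here.

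The settings also tried were RLE size factors, total counts without a scaling factor, every gene with at least 1 count, a strict filter of at least 1 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom, the replicate block, a fit of only the 2 groups compared, a minimum change of 1.5-fold, the omission of each library in turn, and, for lists, an estimated correlation, fry and the block. A fit without the 4 libraries numbered 2, camera without them, the estimated correlation in the fit with the block, and the naming of genes in the HOXB13 comparisons from the fit with the block were added after the data were seen. The rule on single samples far from their group needs at least 4 samples and was not applied to groups of 3.

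The tests were tested on simulated data with the sample sizes, depths and spread of the libraries. Counts were drawn independently for each gene and library, so differences shared by replicate number or between genes were absent. Each share below rests on 66 or 67 genes of a single draw and is rough. Of genes given a 2-fold change, 55.2% were recovered for estradiol in control cells, 70.1% for estradiol in HOXB13 cells, 74.6% for HOXB13 in vehicle, 67.2% for HOXB13 in estradiol and 46.3% for the interaction. At 1.5-fold these shares were 13.4%, 29.9%, 20.9%, 17.9% and 7.46%, and at 4-fold 89.4%, 95.5%, 95.5%, 90.9% and 80.3%. False calls numbered 7, 10, 8, 1 and 11 among 14799 genes.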

Results

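RNA sequencing profiled gene expression in T47D, an established human breast cancer cell line that expresses the estrogen receptor, with or without ectopic HOXB13, a homeobox transcription factor of the posterior HOXB cluster. Cells of both genotypes received the ethanol vehicle or 2 nM estradiol for 24 h, after 72 h in charcoal-stripped serum, which is depleted of steroid hormones. The 4 groups were control cells in vehicle, control cells in estradiol, HOXB13 cells in vehicle and HOXB13 cells in estradiol, with 3 libraries each and 12 libraries in all. The labels call the control cells wild type or normal and do not say whether they carried an empty vector. Total counts ranged from 17679824 to 21385996 per library, 18556 to 19337 genes had at least 1 count in a library, and 14799 genes were tested. The normalised read counts (CPM) of libraries in a group were correlated at 0.979 to 0.989 on the log2 scale, across genes, and every such pair differed by more than counting noise (chi-square per degree of freedom 7.03 to 46.3).

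The first principal component of the log2 CPM, with 35.5% of the variance, parted estradiol from vehicle libraries in both genotypes. The second, with 17.8%, set the 4 libraries numbered 2 apart from the other 8, and these came from all 4 groups. The third, with 8.37%, parted the 6 HOXB13 from the 6 control libraries. Mitochondrial transcripts took 5.63 to 8.51% of the counts, with group means of 6.95% ± 0.382 and 6.40% ± 0.661 in control cells in vehicle and estradiol and 7.38% ± 1.0 and 6.15% ± 0.710 in HOXB13 cells (SD, n = 3). Among markers of blood, vascular, stromal and fat cells, PTPRC, the leukocyte antigen CD45, did not exceed 0.207 CPM in any library, and the endothelial cadherin CDH5 had 0 counts. The highest were the collagen gene COL1A1, at 50.5 to 64.7 CPM, and the pericyte gene RGS5, at 0.966 to 8.10 CPM.

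HOXB13 itself was checked first, because it defines the genotypes. It had 112, 106 and 108 counts in the HOXB13 libraries in vehicle and 110, 92 and 97 in those in estradiol, against 2, 0 and 1 in control vehicle libraries and 0 in all 3 control estradiol libraries. The level in HOXB13 cells was 5.60 ± 0.0452 CPM in vehicle and 5.30 ± 0.525 CPM in estradiol (SD, n = 3), above 29.4% and 28.6% of the tested genes in those groups. In vehicle, the ratio to control cells was 112, with an exact 95% interval of 38.0 to 546. In estradiol, where control cells had 0 counts, HOXB13 was at least 106.7-fold higher than a floor of 3 counts over the group, and the exact 95% lower limit of the ratio was 86.3. Such intervals and floors cover counting error only. Counts per gene symbol do not separate the introduced copy from the cells' own gene.

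The estradiol response of control cells was the reference for the study's question, how HOXB13 affects gene expression with and without the hormone. Estradiol raised classical targets of the estrogen receptor: GREB1, a cofactor of the receptor, went from 157 ± 42.9 to 529 ± 119 CPM (SD, n = 3; 3.37-fold), and MYC, a transcription factor that drives growth, from 8.69 ± 0.295 to 34.8 ± 5.51 CPM (4.0-fold). All 44 tested genes of DNA replication and the G1/S transition rose, among them E2F1, a transcription factor of S-phase genes, from 38.2 ± 1.40 to 109 ± 4.34 CPM (2.84-fold). ERBB2, the HER2 receptor tyrosine kinase, fell from 755 ± 75.4 to 320 ± 12.5 CPM, and CCNG2, an antiproliferative cyclin, from 80.6 ± 10.2 to 33.0 ± 2.35 CPM. In all, 1280 genes rose and 995 fell of the 14799 tested by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, and 396 and 193 of these changed at least 2-fold. With the replicate number as a block, 2594 rose and 2438 fell. The number of genes that fell was 626 without control vehicle library 1, 647 without control estradiol library 2 and 587 without control estradiol library 3.

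**Figure D1:**
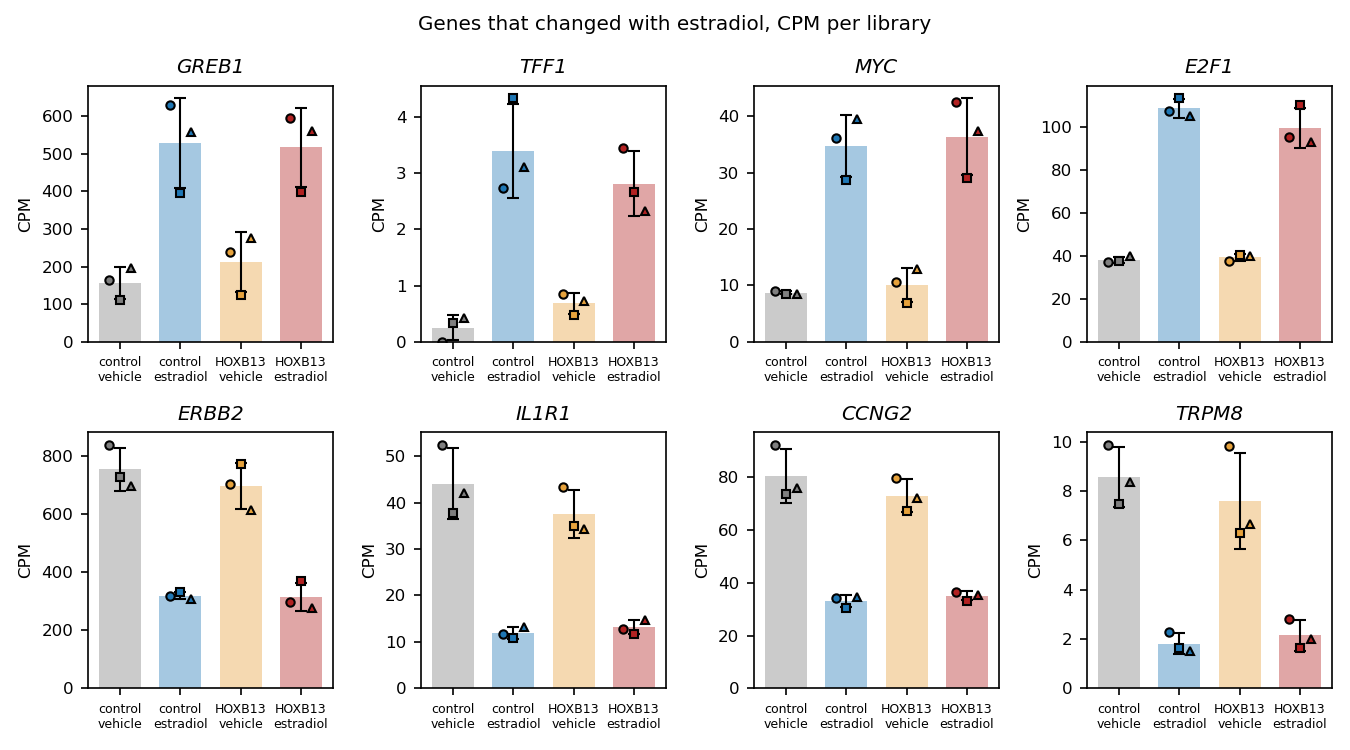
Levels of 8 genes that changed with estradiol in both genotypes, as CPM (y axis, from 0) in the 4 groups (x axis); bars are means of 3 libraries, error bars their SD, and marker shape gives the replicate number (circle 1, square 2, triangle 3). GREB1, TFF1, MYC and E2F1 stood higher and ERBB2, IL1R1, CCNG2 and TRPM8 lower in every estradiol library than in any vehicle library of the same genotype.

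The largest increases in control cells, among genes that the naming rule admits, were in SPINK4, a secreted protease inhibitor (log2 fold change 5.12), the non-coding RNA LINC01016 (4.90), the neurexophilin NXPH3 (4.38), the potassium channel KCNK5 (4.05), the adrenergic receptor ADRA2A (3.73), the glycosyltransferase GALNT5 (3.64), the cation exporter SLC47A1 (3.52) and the scaffold protein PDZK1 (3.37). The largest decreases were in the cold-sensing channel TRPM8 (−2.23), CBLN2 (−2.21), C2orf54 (−2.19), the transcription factor MAF (−2.17), the water and glycerol channel AQP3 (−2.04), the glutamate receptor GRM4 (−2.02), the potassium channel KCNC1 (−1.96) and NDRG1 (−1.95), a gene induced by hypoxia and androgen. SPINK4 and LINC01016 were under 1 CPM in vehicle. TFF1, a secreted trefoil peptide long used as an estrogen marker, went from 0.251 ± 0.221 to 3.39 ± 0.838 CPM (3.72 ± 0.53, SE; adjusted p = 0.000286). CCND1, which encodes cyclin D1, rose by 0.81 ± 0.14 (adjusted p = 0.00141). PGR, the progesterone receptor, rose by 0.91 ± 0.22 (adjusted p = 0.0120; 0.0515 without control estradiol library 1). IL17RB, whose ratio to HOXB13 has been studied as a marker of recurrence, rose by 0.77 ± 0.18 (adjusted p = 0.0101; 0.0536 without control vehicle library 1).

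The estrogen receptor gene ESR1 was at 159.6 ± 43.9 and 146 ± 32.4 CPM without a change past the threshold (log2 fold change −0.13, adjusted p = 0.802). FOXA1, a pioneer factor for the receptor, had a log2 fold change of −0.32 (adjusted p = 0.0669, 0.00045 with the replicate block). GATA3, a luminal transcription factor, had −0.30 (0.0574, 0.0028 with the block). The calls for FOXA1 and GATA3 therefore depended on the block, and both also passed without control vehicle library 2 (adjusted p = 0.0436 and 0.0493).

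Of the lists of genes, estrogen-induced genes rose as a group in control cells. Of 54 tested members, 42 rose, 0 fell and 12 did not pass (50 rose and 1 fell adjusted over the list alone), with a median log2 fold change of 1.11 (camera adjusted p = 1.3e-54). Examples are STC2, a secreted glycoprotein, from 151 ± 40.5 to 787 ± 131 CPM, RAPGEFL1 (2.30) and ZNF703 (1.53), a transcriptional cofactor amplified in luminal tumours. Among 25 estrogen-repressed genes, 0 rose, 15 fell and 10 did not pass (18 fell adjusted over the list alone; median −0.86, camera adjusted p = 2.7e-19), with IL1R1, the interleukin receptor, at −1.89, BCAS1 at −1.74 and CCNG2 at −1.29. The 44 genes of DNA replication and G1/S all rose, also adjusted over the list alone (median 1.23, camera adjusted p = 1.9e-81); RRM2, the ribonucleotide reductase subunit, rose by 1.54, the helicase gene MCM2 by 1.41 and GINS2 by 1.34. Of 40 genes of mitosis and G2/M, 35 rose, 0 fell and 5 did not pass (37 rose adjusted over the list alone; median 0.70, camera adjusted p = 1.3e-25), with ESPL1, which encodes separase, at 1.14 and CDK1 at 0.93. Of 35 ribosome biogenesis genes, 22 rose, 0 fell and 13 did not pass (31 rose adjusted over the list alone; median 0.46, camera adjusted p = 1.3e-12), with NOP56 at 0.95 and DKC1, the rRNA pseudouridine synthase, at 0.82.

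Androgen receptor targets and prostate luminal genes fell as a group in control cells. Of 24 tested members, 1 rose, 13 fell and 10 did not pass, with the same counts adjusted over the list alone (median −0.55, camera adjusted p = 1.6e-08), led by KCNMA1, a potassium channel (−1.45), NDRG1, TRPM8 and MAF. Of 29 luminal identity genes, 2 rose, 11 fell and 16 did not pass (3 rose and 15 fell adjusted over the list alone; median −0.36, camera adjusted p = 5.9e-05). In this list the adhesion molecule CEACAM6 (−1.59) and CLDN4, a tight junction claudin (−0.73), fell and the secretory protein AGR3 (1.5) rose; the list had an adjusted p = 0.087 with an estimated correlation. Of 24 cholesterol synthesis genes, 9 rose, 1 fell and 14 did not pass (13 rose and 1 fell adjusted over the list alone; median 0.35, camera adjusted p = 0.0015, adjusted p = 0.19 with an estimated correlation). ACAT2 (0.72) and the sterol isomerase EBP (0.69) were among those that rose. The other 6 lists that passed in control cells kept their call with an estimated correlation, though with the block as well mitosis genes had an adjusted p = 0.095.

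The other 11 tested lists did not pass in control cells (camera adjusted p 0.323 to 0.979, medians −0.25 to 0.15), though some members did. Of 25 hypoxia and glycolysis genes, 5 rose and 4 fell (6 and 5 adjusted over the list alone), among them PFKFB3, a regulator of glycolysis (1.57), and NDRG1. Of 29 unfolded protein response genes, 3 rose and 4 fell (4 and 6 adjusted over the list alone), with CHAC1 at 1.54 and SEC24D at −0.56. Among 35 type I interferon response genes, 2 rose and 3 fell, with OAS3 at 0.70 and OAS2 at −1.11. Of 14 mesenchymal transition genes, 3 rose and 2 fell, with fibronectin, FN1, at −0.91. Of 17 NF-kB and inflammatory cytokine genes, 1 rose (IER3, 0.73) and 2 fell, including BCL3 (−0.56). Of 22 p53 target and senescence genes, 2 rose, including LMNB1, which encodes lamin B1 (0.97), and 1 fell (BTG2, −0.62). The 24 fatty acid synthesis genes and the 16 basal and myoepithelial genes each had 1 member higher, including the desaturase gene FADS1 (0.54), and 1 lower. From the interferon list on, the counts of these 6 lists were the same adjusted over the list alone. Of 19 HOX cluster genes, 1 rose (HOXB5, 1.78) and 2 fell (2 and 2 adjusted over the list alone), including HOXC10 (−0.43). Of 11 HOX cofactor genes, 0 rose and 1 fell, with the same counts adjusted over the list alone. Of 9 tested non-epithelial cell markers, only CD34 passed, also adjusted over the list alone, from 0.0660 ± 0.0258 to 1.28 ± 0.301 CPM. Of the list of epithelial cells of other origin, 2 members were tested, UPK2 and ACPP, and neither passed in any comparison.

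**Figure D2:**
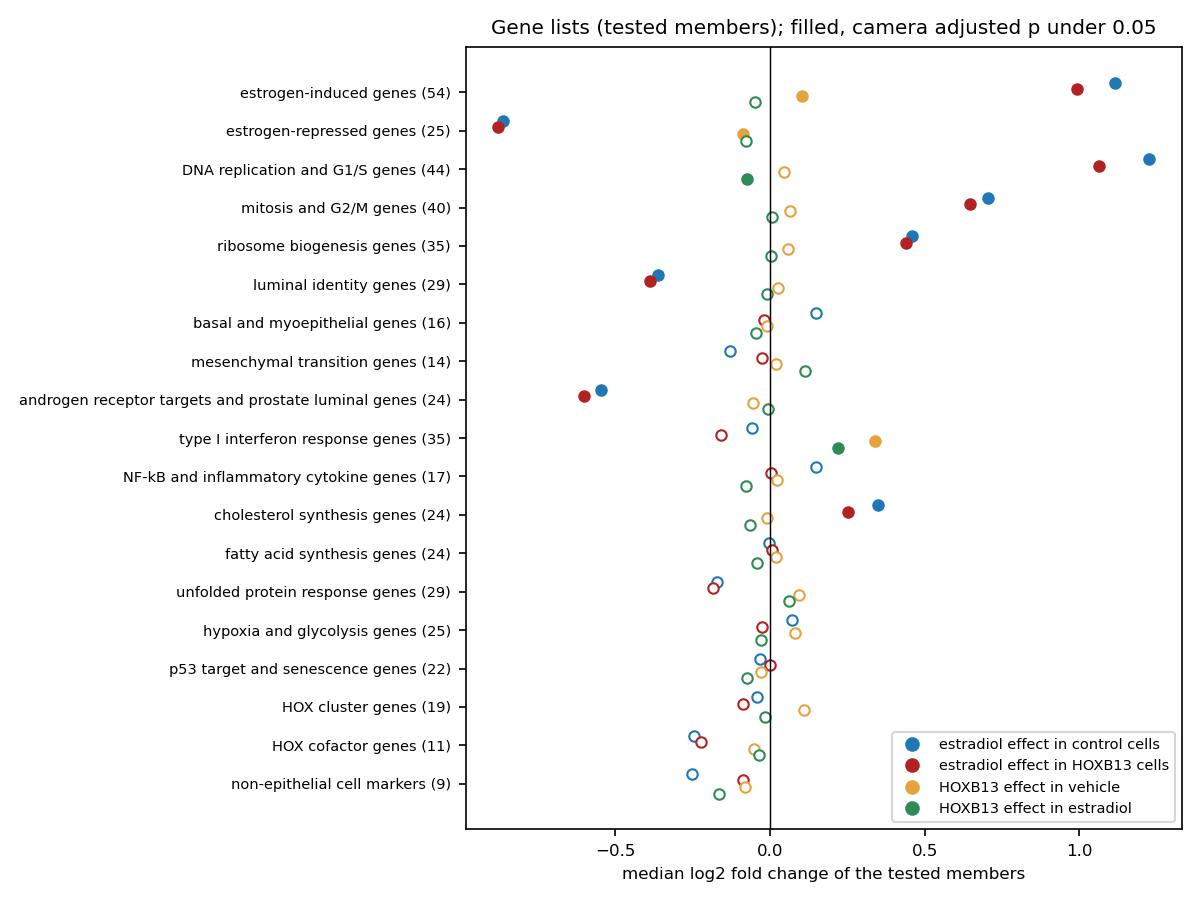
Median log2 fold change (x axis) of the tested members of 19 gene lists (y axis, number of members in brackets) in the 4 comparisons between 2 groups; filled circles have a camera adjusted p under 0.05. The medians of the estrogen-induced (1.11 and 0.99) and DNA replication (1.23 and 1.06) lists for estradiol stand far to the right. For HOXB13 the largest median in size of a list past the threshold was 0.34, for type I interferon response genes in vehicle. That call was lost with an estimated correlation (camera adjusted p = 0.45).

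HOXB13 cells changed the same kinds of genes with estradiol as control cells. GREB1 went from 213 ± 80.1 to 517 ± 104 CPM (SD, n = 3; 2.43-fold), MYC from 10.1 ± 3.06 to 36.4 ± 6.85 (3.60-fold) and E2F1 from 39.2 ± 1.5 to 99.5 ± 9.25 (2.54-fold). ERBB2 fell from 698 ± 78.6 to 314 ± 48.8 CPM and CCNG2 from 73.0 ± 6.37 to 35.0 ± 1.68 CPM. By edgeR's quasi-likelihood test, 1068 genes rose and 944 fell at an adjusted p under 0.05, 309 and 159 of them at least 2-fold. With the replicate block, 2297 rose and 2222 fell. The counts were 689 and 539 without HOXB13 vehicle library 1 and 701 and 527 without HOXB13 estradiol library 1, and 564 genes fell without HOXB13 estradiol library 3.

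In HOXB13 cells the largest increases were in SPINK4 (5.19), LINC01016 (3.79), KCNK5 (3.40), PDZK1 (3.34), NXPH3 (3.17), RASGRP1, an activator of RAS (2.84), the transcription factor TFCP2L1 (2.80) and TRH, the precursor of thyrotropin-releasing hormone (2.73). The largest decreases were in MAF (−2.45), the chemokine receptor CXCR4 (−2.23), C2orf54 (−2.13), KCNC1 (−2.01), RGAG4 (−2.00), GRM4 (−2.00), NDRG1 (−1.96) and the cholesterol transporter ABCA1 (−1.93). TFF1 rose from 0.684 ± 0.189 to 2.81 ± 0.578 CPM (2.03 ± 0.46, SE; adjusted p = 0.00962), CCND1 by 0.63 ± 0.14 (0.00824) and IL17RB by 0.95 ± 0.18 (0.00328). PGR had a log2 fold change of 0.65 ± 0.22 (adjusted p = 0.0687, 0.00011 with the replicate block and 0.0439 without HOXB13 vehicle library 1). ESR1 had −0.22 (0.666, 0.028 with the block). FOXA1 fell by 0.38 (adjusted p = 0.0347), a call that ended in 5 of the 6 fits that left out 1 library (0.0686 to 0.155), all but the fit without HOXB13 vehicle library 2. GATA3 fell by 0.43 (0.010; 0.0596 without HOXB13 vehicle library 1).

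The same 8 lists passed as in control cells. Estrogen-induced genes had 39 of 54 members higher and 1 lower (44 and 1 adjusted over the list alone; median 0.99, camera adjusted p = 1.7e-45), with PDZK1, RAPGEFL1 (2.08), STC2 (1.94) and ZNF703 (1.15) as examples. Estrogen-repressed genes had 0 of 25 higher and 16 lower (17 adjusted over the list alone; median −0.88, camera adjusted p = 1.2e-19), with the growth factor TGFB3 at −1.07 and IL1R1 at −1.52. All 44 DNA replication and G1/S genes rose (44 adjusted over the list alone; median 1.06, camera adjusted p = 5.5e-76), including RRM2 (1.38) and MCM2 (1.24). In the mitosis and G2/M list, 34 of 40 rose and 0 fell (38 adjusted over the list alone; median 0.65, camera adjusted p = 5.4e-26), with CDK1 at 0.94 and BUB1, a spindle checkpoint kinase, at 0.87. Ribosome biogenesis genes had 16 of 35 higher and 0 lower (26 adjusted over the list alone; median 0.44, camera adjusted p = 3.6e-12), including NOP56 (0.83) and NOLC1 (0.55). Androgen receptor targets had 1 of 24 higher and 11 lower (1 and 15 adjusted over the list alone; median −0.60, camera adjusted p = 9.2e-09), with NDRG1, MAF, TRPM8 (−1.82) and KCNMA1 (−1.24). Luminal identity genes had 1 of 29 higher and 13 lower (2 and 16 adjusted over the list alone; median −0.39, camera adjusted p = 2.7e-07), with CEACAM6 at −1.70 and the transcription factor TFAP2A at −0.77. Cholesterol synthesis genes had 6 of 24 higher and 1 lower (10 and 1 adjusted over the list alone; median 0.25, camera adjusted p = 0.0109), including ACAT2 (0.72), and an adjusted p = 0.32 with an estimated correlation; the other 7 lists kept their call with it, though with the block as well mitosis and luminal identity genes each had an adjusted p = 0.087. The remaining 11 lists did not pass (camera adjusted p 0.220 to 0.917, medians −0.22 to 0.01). Members of these that passed include HSPA5, the endoplasmic reticulum chaperone BiP (−0.56), DDIT4, an inhibitor of mTOR signalling (−1.36), BCL3 (−1.01), FN1 (−0.81) and CD34 (2.85).

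The gene-by-gene test of whether the estradiol response differed between HOXB13 and control cells called 0 genes. The difference in log2 fold change was −1.70 ± 0.72 (SE) for TFF1, −0.47 ± 0.39 for GREB1, −0.26 ± 0.31 for PGR, −0.15 ± 0.29 for MYC, −0.18 ± 0.20 for CCND1 and 0.18 ± 0.26 for IL17RB, each at an adjusted p = 1.0 by edgeR's quasi-likelihood test. At an unadjusted p under 0.05 there were 219 genes, where 740 of the 14799 would pass if none differed. With the replicate number as a block there were 585, and 0 genes were called. Without the block, the difference of the libraries numbered 2 counts as spread within groups. Both 219 and 585 lie below 740, so the p-values of this test ran larger than if no gene differed. The 0 calls therefore do not show equal responses. DESeq2 and limma-voom also called 0 higher and 0 lower. Without the block, the median 95% interval of the difference reached 0.51 to either side (log2 scale) for 12109 genes of moderate or high expression. Simulated data held no differences shared by replicate number. In them, this test recovered 7.46% of genes given a 1.5-fold difference, 46.3% at 2-fold and 80.3% at 4-fold.

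Of the genes called in both genotypes, 911 rose and 709 fell in both, against 92.4 and 63.5 shared by independent lists of those lengths, and 0 went opposite ways. The 2 comparisons share no library. Another 655 genes were called in control cells alone, of which 637 had the same sign in HOXB13 cells, and 392 in HOXB13 cells alone, of which 384 had the same sign in control cells; the interaction test called 0 of either set. Across all 14799 tested genes, Pearson's r between the responses of the genotypes was 0.738. Over the 4158 genes with an average estradiol effect over both genotypes at an adjusted p under 0.05, the slope of the HOXB13 on the control response through the origin was 0.848, and 0.814, 0.828 and 0.790 within the 3 replicate numbers (mean 0.811, SD 0.0189). Noise in the control responses pulls this slope towards 0, also where the responses are equal. By total least squares, which treats both responses alike, the slope was 0.906, and 0.905, 0.955 and 0.899 within the replicate numbers (mean 0.920, SD 0.0304). Genes are not independent replicates, so no p is given for either slope. The first slope was 0.775 over genes called in control cells and 0.911 over genes called in HOXB13 cells.

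**Figure D3:**
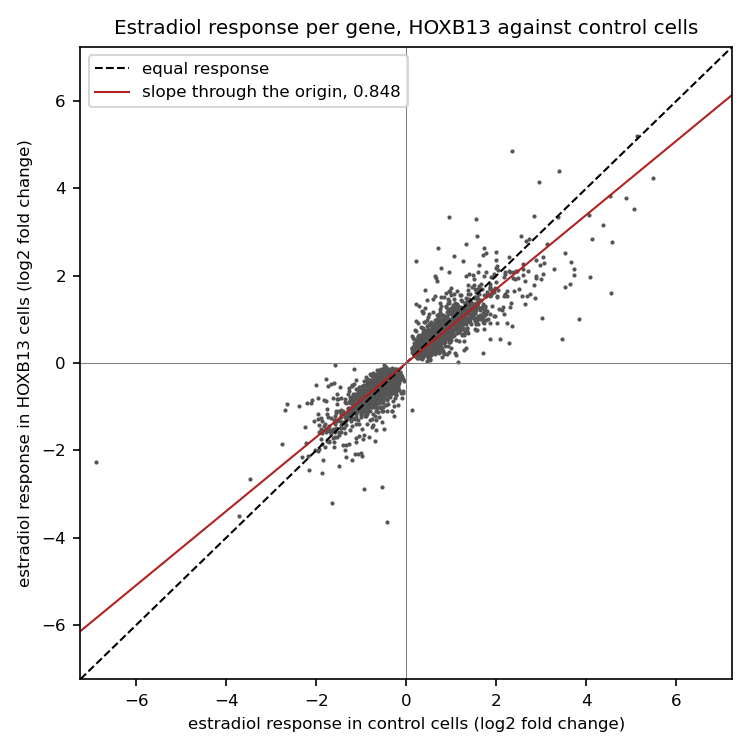
Estradiol response (log2 fold change) in HOXB13 cells (y axis) against control cells (x axis) for the 4158 genes with an average estradiol effect past the threshold, each point a gene. The solid line through the origin has the fitted slope of 0.848, which noise in the control responses lowers, and the dashed line marks equal responses.

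Among the lists, estrogen-induced genes passed the test of the difference, with 8 of 54 positive (median −0.17, camera adjusted p = 5.5e-07), but not with an estimated correlation (adjusted p = 0.71 with an estimated correlation). Examples are WISP2, a secreted matricellular protein (−1.28), the chemokine CXCL12 (−0.63) and ZNF703 (−0.37). DNA replication and G1/S genes had a positive difference in 8 of 44 (median −0.13, camera adjusted p = 0.00044; adjusted p = 0.80 with an estimated correlation), such as the chromatin assembly factor CHAF1B (−0.56) and the licensing factor CDT1 (−0.34). In both lists 0 members passed singly, also adjusted over the list alone. The other 17 lists did not pass (camera adjusted p 0.408 to 0.909), with 0 members past the threshold in any of them.

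The comparison of HOXB13 with control cells in vehicle addressed the effect of HOXB13 without added estradiol. Besides HOXB13, the gene that stood out was BCHE, which encodes the secreted esterase butyrylcholinesterase: it went from 11.6 ± 1.74 CPM in control cells to 29.6 ± 2.99 CPM in HOXB13 cells (SD, n = 3; 2.54-fold, log2 fold change 1.34 ± 0.16, adjusted p = 0.00542). The only other call was the transcript RP11-206M11.7 (1.31, adjusted p = 0.0227), which has a clone-type name and was named after its values were seen. In all, 3 genes were higher and 0 lower by edgeR's quasi-likelihood test, with 559 genes at an unadjusted p under 0.05 where 740 would pass by chance; DESeq2 called 13 higher and 7 lower, and limma-voom 5 and 1. With the replicate block, 28 were higher and 32 lower, and 1421 genes had an unadjusted p under 0.05. Without it, 559 lies below 740, so those p-values ran large, and 3 calls do not show that few genes differed. Without control vehicle library 3, HOXB13 alone passed and BCHE had an adjusted p = 0.0642, within a range of 9.4e-12 to 0.0642 over 15 alternatives; without HOXB13 vehicle library 2, 6 genes were higher.

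With the replicate block, the genes higher in HOXB13 cells in vehicle included WISP2 (1.84), ADRA2A (1.62), the chloride channel accessory protein CLCA2 (1.46), ANGPT1, which encodes the vascular ligand angiopoietin-1 (1.29), NXPH3 (1.12) and SUSD3 (0.90). Those lower included the transcription factor TFAP2B (−1.60), the synaptic adhesion protein NLGN1 (−1.47), the heparan sulfate endosulfatase SULF2 (−1.13), the protocadherin PCDH7 (−0.76), ARL11 (−0.75) and SPNS2, a sphingosine-1-phosphate transporter (−0.67). In edgeR's fit of all 12 libraries without the block, each of these 12 genes missed the threshold, with CLCA2 and ANGPT1 nearest at an adjusted p = 0.0521 each, while CLCA2 (0.0229) and ANGPT1 (0.0393) passed by limma-voom. WISP2 passed without control vehicle library 2 (0.0179), and ADRA2A (0.00420) and ANGPT1 (0.0433) passed without HOXB13 vehicle library 2. DESeq2, also without the block, called 9 genes that the naming rule admits in this comparison and that missed the threshold in edgeR's fit. These may include genes not reported here. The fixed genes of the estrogen receptor axis had small estimates here: ESR1 0.11, PGR 0.23, GREB1 0.44, IL17RB −0.13, FOXA1 0.14, GATA3 0.08, CCND1 0.12 and MYC 0.22, each at an adjusted p = 1.0. TFF1 had 1.43 ± 0.60 (adjusted p = 1.0).

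**Figure D4:**
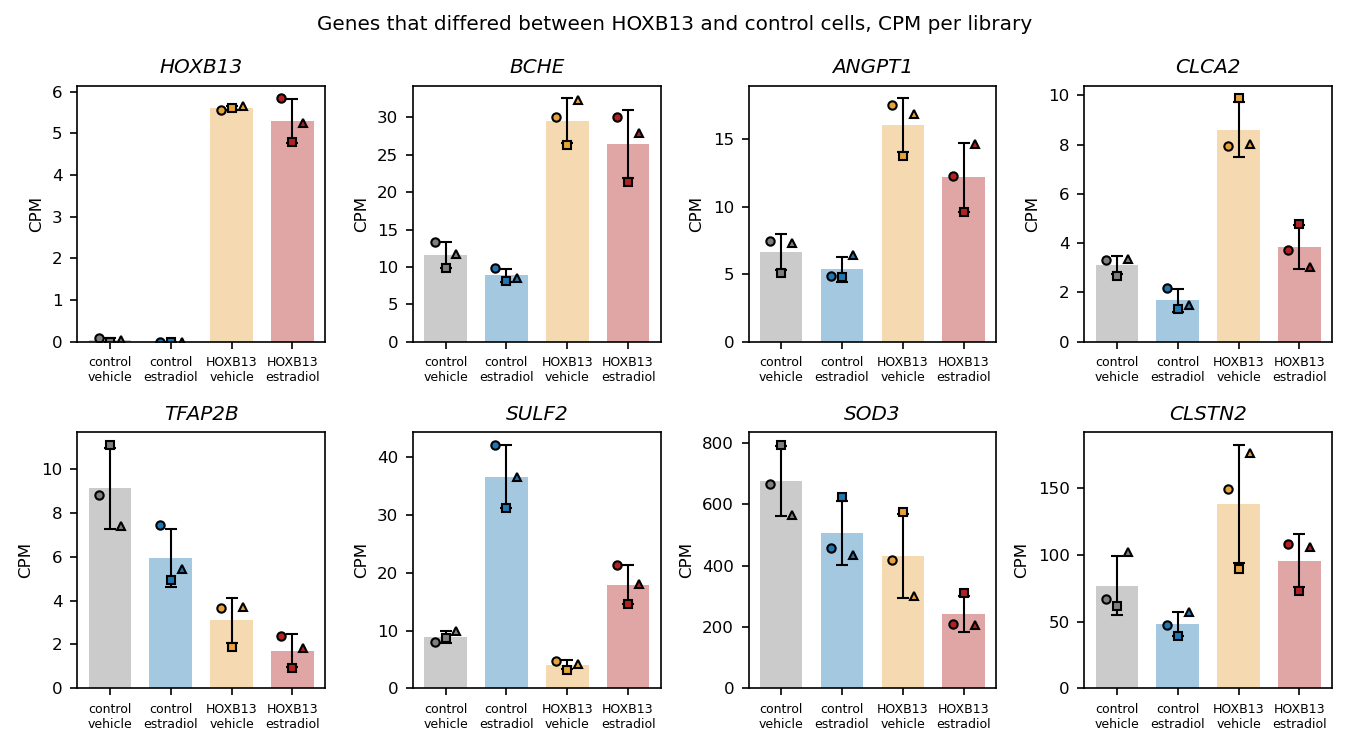
Levels of 8 genes that differed between HOXB13 and control cells, as CPM (y axis, from 0) in the 4 groups (x axis); bars are means of 3 libraries, error bars their SD, and marker shape gives the replicate number (circle 1, square 2, triangle 3). In edgeR's fit of all 12 libraries, HOXB13 and BCHE passed in vehicle and in estradiol without the block, and the other 6 genes passed in both with the block but not without it.

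Type I interferon response genes passed as a list in vehicle, with 31 of 35 higher in HOXB13 cells (median 0.34, camera adjusted p = 3.6e-10), a call lost at an adjusted p = 0.45 with an estimated correlation. Members included OAS1 (1.23), an RNA-sensing antiviral enzyme, and the antiviral GTPase MX1 (0.79), at 52.6 ± 19.4 CPM in control and 90.7 ± 35.6 CPM in HOXB13 cells, and 0 members passed singly or adjusted over the list alone. The replicates spread widely: relative to the control vehicle mean, the mean log2 level of the list was −0.25, 0.03 and 0.22 in the 3 control vehicle libraries and 0.37, 0.00 and 0.72 in the 3 HOXB13 vehicle libraries. Estrogen-induced genes had 39 of 54 positive (median 0.10, camera adjusted p = 1.4e-05; adjusted p = 0.45 with an estimated correlation), with WISP2 and SUSD3 the 2 members past the threshold adjusted over the list alone and 0 over all genes. Estrogen-repressed genes had 7 of 25 positive (median −0.09, camera adjusted p = 0.037; adjusted p = 0.45 with an estimated correlation), with 0 past the threshold on either basis; PIK3IP1 had −0.43 and HES1 −0.44. The other 16 lists did not pass (camera adjusted p 0.0532 to 0.988), with 0 members past the threshold over all genes and, adjusted over the list alone, 1 basal gene higher and 1 non-epithelial marker lower; with the replicate block, the mitosis (0.025) and unfolded protein response (0.0037) lists also passed, calls lost in that fit with an estimated correlation (adjusted p = 0.914 and 0.499).

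In estradiol, HOXB13 cells again had higher BCHE, at 26.4 ± 4.53 CPM against 8.88 ± 0.919 CPM in control cells (SD, n = 3; 2.97-fold, log2 fold change 1.57 ± 0.16, adjusted p = 0.00101), and this call held under all 15 alternatives (largest adjusted p 0.0188). HOXB13 and BCHE were the 2 genes higher, and 0 were lower, by edgeR's quasi-likelihood test, with 489 genes at an unadjusted p under 0.05 where 740 would pass by chance; DESeq2 called 11 higher and 9 lower, and limma-voom 3 and 2. With the replicate block, 21 were higher and 37 lower, and 1518 genes had an unadjusted p under 0.05. The 489 without it lie below 740, so the 2 calls of that fit do not show that few genes differed. Those higher included the gap junction protein GJA1, connexin 43 (1.97), CBLN2 (1.84), the kinase STK32B (1.46), CLCA2 (1.19), ANGPT1 (1.17) and the synaptic calsyntenin CLSTN2 (0.99). Those lower included TFAP2B (−1.80), ANK1, which encodes an ankyrin (−1.08), SOD3, the extracellular superoxide dismutase (−1.07; 505.9 ± 104 CPM in control and 242 ± 59.2 CPM in HOXB13 cells), SULF2 (−1.03), EYA2 (−0.92), UPK3B (−0.69) and PTRF, the caveolar protein cavin-1 (−0.67). In edgeR's fit of all 12 libraries without the block these 13 genes did not pass, with adjusted p from 0.107 upwards. GJA1 (0.0274) and SULF2 (0.0335) passed by limma-voom, and GJA1 with only the 2 groups compared (0.000399). DESeq2, also without the block, called 10 genes that the naming rule admits in this comparison and that missed the threshold in edgeR's fit. These may include genes not reported here.

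Of the genes called with the block, 7 were higher and 15 lower in HOXB13 cells both in vehicle and in estradiol, against 0.0397 and 0.0800 for independent lists of those lengths, and 0 changed direction; the 2 comparisons share no library. In estradiol, type I interferon response genes had 29 of 35 positive (median 0.22, camera adjusted p = 6.9e-06; adjusted p = 0.76 with an estimated correlation). PARP9 (0.54) passed singly with the block (adjusted p = 0.0085) but not without it (0.655). DNA replication and G1/S genes had 9 of 44 positive (median −0.07, camera adjusted p = 0.033; adjusted p = 0.76 with an estimated correlation), such as the uracil glycosylase UNG (−0.24) and the flap endonuclease FEN1 (−0.18). In both lists 0 members passed over all genes or adjusted over the list alone. The other 17 lists did not pass (camera adjusted p 0.177 to 0.920), with 0 members past the threshold over all genes and, adjusted over the list alone, 1 androgen receptor target and 1 inflammatory gene lower; with the replicate block, cholesterol synthesis genes passed (0.049, lower), a call lost in that fit with an estimated correlation (adjusted p = 0.789).

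Across all 14799 tested genes, the average HOXB13 effect was almost uncorrelated with the average estradiol effect (Pearson's r 0.0543, Spearman's rho 0.0251). Genes are not independent replicates. Within each replicate number, r was 0.177, −0.0218 and 0.0183, and it ranged from −0.0444 to 0.153 with 1 library left out, so its sign was not stable. Genes called for the average HOXB13 effect numbered 22, and 386 with the replicate block, so most genes entered the correlation without a called effect. With the block, 110 of the genes lower with HOXB13 were lower with estradiol, against 51.9 for independent lists, and 46 were higher, against 51.8. Of those higher with HOXB13, 52 were higher with estradiol, against 35.9, and 51 lower, against 36.0.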

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

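The splits of the samples were planned, and the 2 tests of the vehicle baseline were chosen after the result was seen. The results below are here because the estradiol response of a gene list differed between genotypes by a test of the difference itself. Estrogen-induced genes responded less in HOXB13 cells (median difference −0.17 on the log2 scale, 8 of 54 genes positive, camera adjusted p = 5.5e-07), as did DNA replication and G1/S genes (median −0.13, 8 of 44 positive, camera adjusted p = 0.00044). With an estimated correlation the adjusted p was 0.71 and 0.80, and edgeR's quasi-likelihood test called 0 single genes, with 219 at an unadjusted p under 0.05 and 0 calls by DESeq2 and limma-voom. The 219 lie below the 740 that would pass if no gene differed, so 0 calls do not show equal responses.

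Whether the difference lay in the vehicle or the estradiol libraries was not settled. Estrogen-induced genes had a median HOXB13 effect of 0.10 in vehicle (camera adjusted p = 1.4e-05; 0.45 with an estimated correlation) and −0.05 in estradiol (0.449). The DNA replication list had 0.04 in vehicle (0.215) and −0.07 in estradiol (0.033; 0.76 with an estimated correlation). Over the 4158 estradiol-responsive genes, the slope of the HOXB13 effect in vehicle on the average estradiol effect was 0.0809, against −0.0147 in estradiol, where it was 0.0716, −0.0724 and −0.0300 in the 3 replicate numbers. Vehicle libraries of both genotypes enter both sides of the first slope, and estradiol libraries enter both sides of the second. Noise in them moves these slopes. With equal group sizes and equal spread, it favours neither sign, since the genotypes enter the HOXB13 effect with opposite signs. The vehicle slope was also taken with control vehicle library 1 left out of the HOXB13 effect only. That library stayed in the average estradiol effect and in the choice of genes, so its part was not fully removed. The slope was then 0.0416, or 51.4% of its full value. This lies between the bounds set for that library as the cause (under 50%) and for excluding it (at least 80%). The vehicle slope was positive in 2 of the 3 replicate numbers (0.159, −0.0178 and 0.0725, SD 0.0885), so a raised baseline of estradiol-responsive genes in HOXB13 cells may contribute and cannot be told apart from a spread between libraries, with 3 replicate numbers too few to decide.

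For the interaction, 100 of the 200 possible splits were drawn, and all 100 gave at least the real count of 0 genes, an outcome that a count of 0 fixes in advance and that says nothing about chance. The highest other count was 2660, and 5 splits made any call. Of the 7 splits that set the libraries numbered 2 apart, 3 made calls, the largest among them with 2660, and of the other 93, 2 made calls, with at most 22. Such a count, far above the real one, points to a structure of the samples by replicate number. For the comparisons between 2 groups the 10 splits are too few for a share under 0.05: for each, 1 of 10 splits gave as many genes, the real one, with 2275 for estradiol in control cells, 2012 for estradiol in HOXB13 cells, 3 for HOXB13 in vehicle and 2 for HOXB13 in estradiol, and the highest other count was 0. Only 4 of the 10 splits part all 3 pairs of equally numbered libraries, and with the block the real ones gave 5032, 4519, 60 and 58 genes, against 0 for the highest other. Every other split mixes the 2 real groups, so a real difference between them adds to the spread within groups and keeps its count low. These counts of 0 therefore do not measure what chance alone would give.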

How the results depend on the processing

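The fit without the 4 libraries numbered 2, camera without them and the estimated correlation in the fit with the block were chosen after the data were seen. No named gene and no list past its threshold changed direction under an alternative. Other called genes were not checked for direction one by one. Of list results under an alternative, 435 stayed on the same side of the threshold, 31 lost their call and 9 gained it. Of those of named genes, 3442 stayed, 69 lost and 132 gained it. Direction was compared only for results past the threshold before the alternative was applied. Results short of it may have changed sign. RLE size factors, total counts and the strict filter kept every count of genes within 1.5 times its value, and the scalings moved the median of all genes to between −0.0129 and 0.0336. With total counts, the share of higher calls for estradiol in HOXB13 cells went from 53.1% to 62.5%. The cause was not tested for any change below unless it is given.

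With the replicate block, 2594 genes were higher and 2438 lower for estradiol in control cells, 2297 and 2222 for estradiol in HOXB13 cells, 28 and 32 for HOXB13 in vehicle, 21 and 37 for HOXB13 in estradiol, and 0 and 0 for the interaction (585 at an unadjusted p under 0.05, smallest adjusted p 0.468). Among the fixed genes given here it changed the calls of PGR and ESR1 in HOXB13 cells and of FOXA1 and GATA3 in control cells, and no other. Against a minimum change of 1.5-fold, a stricter question, 268 were higher and 94 lower for estradiol in control cells, 164 and 61 in HOXB13 cells, and 1 higher for HOXB13 in vehicle. DESeq2 gave 13 and 7 for HOXB13 in vehicle and 11 and 9 in estradiol. Limma-voom gave 5 and 1 in vehicle and 2 lower in estradiol. These included ANGPT1 and CLCA2 higher in vehicle, GJA1 higher and SULF2 lower in estradiol, and AC073464.6 lower in both, the last chosen after its values were seen.

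With every gene that had a count, 37 genes were higher and 25 lower for HOXB13 in vehicle, 16 and 14 in estradiol, and 3 and 1 for the interaction, and the response ratio was 0.825. The interaction calls were RMRP (2.10), RN7SK (1.83) and RNA28S5 (0.98) higher and ADRA2A (−1.56) lower, named after their values were seen. With only the 2 groups compared, which leaves fewer libraries to estimate the spread, 1 gene was higher for HOXB13 in vehicle, and BCHE had an adjusted p = 0.0639, in a range of 9.4e-12 to 0.0642 over its 15 alternatives. In estradiol 3 were higher there, with GJA1 added (adjusted p = 0.00040; 1.9e-19 to 0.726 over 15 alternatives). Without the 4 libraries numbered 2, 1650 were lower for estradiol in control cells, 1741 higher and 1544 lower in HOXB13 cells, 28 and 9 for HOXB13 in vehicle, 8 and 13 in estradiol, and 1 lower for the interaction (ADRA2A, −2.00, adjusted p = 0.0142), with a ratio of 0.790. In that fit GREB1 passed for HOXB13 in vehicle (0.52, adjusted p = 0.0318; 0.0318 to 1.0 over 15 alternatives). Over all genes called in control cells the ratio was 0.775, and over all those called in HOXB13 cells 0.911, since each choice selects for large values in its own genotype.

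With 1 library left out, genes higher and lower for estradiol ranged from 861 to 1500 and 587 to 1258 in control cells and from 689 to 1048 and 527 to 824 in HOXB13 cells. For HOXB13 in vehicle they ranged from 1 to 6 higher, with 0 lower, and in estradiol they stayed at 2 and 0. The interaction stayed at 0 and 0, the ratio ranged from 0.751 to 0.873, and the relation of the average effects from −0.0444 to 0.153, with a change of sign.

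Of 8 lists past the threshold for estradiol in each genotype, 5 passed in control cells and 5 in HOXB13 cells with the block and an estimated correlation; then mitosis and G2/M genes had an adjusted p = 0.095 and 0.087, luminal identity genes 0.183 and 0.087, and cholesterol synthesis genes 0.37 and 0.50. For HOXB13 in vehicle the 3 lists became 0 with an estimated correlation, 0 with fry, 5 with the block, 0 with both the block and an estimated correlation, and 6 without the libraries numbered 2. For HOXB13 in estradiol the 2 lists became 0, 0 and 0 with an estimated correlation, fry and the block with an estimated correlation, and 1 without the libraries numbered 2. For the interaction the 2 lists became 0, 0, 0 and 4 under the same settings. An estimated correlation allows for members that vary together between replicates, which a preset of 0.01 does not. Small changes can be missed: in simulated data 7.46% of 1.5-fold interactions were recovered. The simulation varied neither depth nor replication and held no differences shared by replicate number.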

Other observations

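The tests of estradiol response or cell cycle state, of copy number and of length for the HOXB13 genes were chosen after the result was seen, and those of length and GC content for the libraries numbered 2 before. Averaged over vehicle and estradiol, the HOXB13 effect drew on 6 libraries per genotype and called more genes, 13 higher and 9 lower by edgeR's quasi-likelihood test and 158 and 228 with the replicate block. BCHE was higher in HOXB13 cells in 6 of 6 pairs of equally numbered libraries (log2 fold change 1.46 with the block, adjusted p = 9.6e-12). ANGPT1, the angiopoietin ligand (1.23, 4.5e-08), CLCA2 (1.32, 3.5e-05), the kinase STK32B (1.23, 0.00236) and WISP2 (1.20, 0.000190) were higher in 6 of 6 pairs, and the connexin GJA1 (1.67, 0.000190) in 5 of 6. TFAP2B (−1.70, 4.6e-06), the synaptic adhesion gene NLGN1 (−1.44, 0.000430), SULF2, which edits heparan sulfate (−1.08, 9.7e-08) and the antioxidant enzyme SOD3 (−0.87, 6.0e-10) were lower in 6 of 6. Without the block, all of these but SOD3 (0.0592) also passed for the average effect, with adjusted p up to 0.0434 (STK32B). Other genes called with the block did not pass without it, such as GALNT5 (1.46, 4 of 6 pairs; adjusted p = 0.244 without the block). CBLN2 (1.18, 5 of 6 pairs, 0.0583) and ANK1 (−0.80, 6 of 6 pairs, 0.349) did not either. The pairs come from the libraries that selected the genes and are no separate support.

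Type I interferon response genes were higher as a list, with 33 of 35 positive (median 0.30, camera adjusted p = 1.6e-11; adjusted p = 0.55 with an estimated correlation). With the block, 110 of the genes lower with HOXB13 were lower with estradiol, against 51.9 for independent lists, and 46 were higher, against 51.8. Of those higher with HOXB13, 52 were higher with estradiol, against 35.9, and 51 were lower, against 36.0. Both average effects use the same 12 libraries. GCOM2 (15 counts in all) and SASH3 (8) had counts in all 6 HOXB13 libraries and no control library, and AC073464.6 (87) in all 6 control libraries and no HOXB13 library; these were chosen after their values were seen, and other splits of the libraries gave up to 7 such genes.

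Libraries numbered 3 and 1 differed by 21 genes, in a fit of those libraries alone. In a fit of all 12 libraries, which has more power, the 4 libraries numbered 2 differed from numbers 1 and 3 by 5899 genes. Of these, 2841 were higher and 3058 lower, pooled over the groups. Across 13072 genes with a known transcript length, the Spearman correlation of this difference with length was −0.522, −0.499, −0.475 and −0.313 in the 4 groups, the smallest in size being −0.313, so the pattern is consistent with a difference in how long and short transcripts were recovered. GC content stays open: its correlation given length was 0.220, 0.206, 0.239 and 0.305 in the 4 groups. The bounds set for it were 0.1 and 0.3, and only the last value, for HOXB13 cells in estradiol, lay above 0.3. A different estradiol response or cell cycle state of the cultures also stays open. The smallest camera adjusted p of the estrogen-induced, estrogen-repressed, DNA replication and mitosis lists was 0.493, and a test that misses the threshold excludes nothing. Across genes, the number 2 difference had a Spearman correlation of 0.148 with the average estradiol effect, not under the 0.1 needed to set this explanation aside. The estrogen-induced list had a median difference of −0.12 (log2 scale), the other way. The labels name no batch, and no other biological explanation was tested.

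The genes called for the average HOXB13 effect with the block were weighed against transcript length and copy number. A first test for length, the correlation of the HOXB13 effect with length over all genes, gave 0.128 and decided nothing, and the test that follows was chosen after that was seen. With each library's length trend taken out, 95.9% of the called genes (355 of 370) were still called the same way, their median change going from 0.326 to 0.316, which argues against length as the whole cause. Copy number differences between the cell populations stay open. The 10 nearest neighbours of the called genes moved the same way by a median of 0.0332 (bootstrap interval 0.0211 to 0.0402). This was 10.1% of the genes' own median change of 0.329, above the 10% bound set for excluding copy number. The upper limit of the interval, 0.0402, also had to lie under that bound and did not. Of 365 placed genes, 36 had neighbours that moved at least 50% as far the same way, a share not computed for other genes. An effect of HOXB13 itself, and of how the cells were selected or of a missing empty vector, were not tested apart, since each follows the genotype.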
